A study of Rattus norvegicus with 24 samples.

How the data were processed

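Gene expression was measured with Illumina rat arrays in colonic epithelial cells of Sprague Dawley rats aged 8 months. The rats were born as controls (C) or with intra-uterine growth retardation (IUGR, R) and were fed chow (normal diet, ND) or a high-fat diet (HFD), which gives the groups CND, CHFD, RND and RHFD. Per the labels, cells from proximal and distal colon were released by incubation with EGTA and EDTA followed by vortexing, and RNA was extracted with Trizol, cleaned on a column and treated with DNase. Per the labels, biotin-labelled cRNA was hybridized and the arrays were read with GenomeStudio; its version, the bead filters and the background setting are not given in the sources used here.

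There were 24 arrays, 6 per group, on 2 chips of 12 arrays, with 3 arrays of every group on each chip. The array titles carry a number with a letter, and 4 of these title numbers (CHFD 10B, RHFD 21B, RHFD 25B and RHFD 3A) stand on 2 arrays each, with 1 array on each chip. The labels do not say whether such arrays come from the same animal, nor what the letter means. Arrays that share a title number are called 1 sample here, which leaves 6 CND, 5 CHFD, 6 RND and 3 RHFD samples, and means and SDs of transcript levels are over these samples. In CND the 3 samples on chip 1 carry the letter A and the 3 on chip 2 the letter B, and all RND samples carry B, so chip and letter cannot be told apart in CND. The log2 values of arrays sharing a title number differed with an SD of 0.248 to 0.279, against 0.377 to 0.701 for the 32 other pairs of the same group on different chips. No title number occurs in more than 1 group, so the groups are not paired.

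The deposited non-normalized table holds, per the file headers, a mean signal intensity for each of 22523 probes on each array. These deposited intensities are whole numbers on a linear scale without background subtraction or scaling between arrays. The deposited table also gives a detection p-value for each probe and array, which compares the probe with the negative control beads of that array. The deposited series matrix holds intensities that the authors quantile normalized on the linear scale without background subtraction, with column medians between 100.2083 and 100.4167.

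The non-normalized intensities were background corrected and quantile normalized with neqc (limma 3.58.1 in R 4.3.3, statmod 1.5.0), with the level of the negative controls inferred from the detection p-values and an offset of 16, which gives values on a log2 scale. Probes with a detection p-value under 0.05 on at least 6 arrays were tested, which left 10193 probes. Of these, 7483 pair with a gene symbol in the platform's table, for 7345 genes. A table of RefSeq genes on the GRCr8 assembly gave current symbols and positions. The number of arrays limits the precision of every value.

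A linear model with the 4 groups and the chip was fitted to all 24 arrays with limma, and arrays sharing a title number were entered as a random block with an estimated correlation of 0.812. The 7 comparisons were the diet effect in control rats, in IUGR rats and averaged over birth status, the IUGR effect on chow, on high-fat diet and averaged over diet, and the interaction of birth status with diet. The Benjamini-Hochberg method adjusted p within each comparison, and probes with an adjusted p under 0.05 are said to pass the threshold. Errors of log2 differences are standard errors (SE) from limma, and intervals of folds are 95% confidence intervals. Where a gene was not detected on any array of the lower group, a lower bound of its fold is also given, for which values below the dimmest detected probe of an array were raised to the level of that probe. This bound compares group means after background correction and includes no sampling error. It is not a confidence limit, and folds without background correction can be smaller. The same functions were tested on simulated data with the spread of these arrays, in 3 simulations with 200 changed probes each: 4-fold changes were recovered for 98.7% of the changed probes in control rats and 96.7% in IUGR rats, and 2-fold changes for 86.0% and 77.7%. False calls made up 3.99% and 5.05% of those calls, and 0 probes were called in the comparisons without a simulated change. The simulated probes varied independently of each other. Genes on the real arrays may vary together, so these simulations do not give the share of false calls there.

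The samples, tests, alternatives, gene lists and the rule for naming genes were set before the data were examined. Under this rule the text names, in each comparison, up to 12 genes with the largest increase and 12 with the largest decrease past the threshold. Where fewer than 10 probes passed, it also names up to 5 genes in each direction with the smallest p, given as not passing. The rule further allowed up to 4 members, by p, of each list that was called or had members past the threshold after adjustment over the list alone. Of these lists and members the text gives a part, chosen after the values were seen. For a gene with several probes the brightest was used.

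The 43 lists held pathways of colon epithelium and metabolism and markers of other cell types, and 35 of them had at least 5 members among the tested genes. The list of mast cell markers also held granulocyte markers, and the list of immediate early genes also held heat shock genes. They were tested with cameraPR at a preset correlation between genes of 0.01, again with a correlation estimated for each list, and with fry, which tests each list by itself. P-values of lists were adjusted over the 35 lists within each comparison.

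The alternatives were no background correction, an offset of 50, scaling to equal medians, the series matrix values, no filter on dim probes, a filter at detection p under 0.01 on every array (5763 probes), no chip term, each chip alone, arrays as independent, arrays sharing a title number averaged, the letter of the title as a term, only the groups compared, array weights, each sample left out in turn and, for the lists, all probes of a gene averaged. An alternative added after the data were seen left Retnlb and Itln1 out of the lists. No array was left out of the values reported.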

Results

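Transcript levels in colonic epithelial cells were measured on 24 arrays from 4 groups of rats: controls on chow (CND, n = 6 samples), controls on high-fat diet (CHFD, n = 5), IUGR rats on chow (RND, n = 6) and IUGR rats on high-fat diet (RHFD, n = 3). Median signal per array ranged from 92 to 112 and mean signal from 309 to 571, and between 8303 and 9872 of the 22523 probes were detected on each array. The mean number of detected probes was 8984 ± 510 (SD, 6 arrays) in CND, 9087 ± 193 in CHFD, 9339 ± 499 in RND and 9288 ± 250 in RHFD. All levels are on a log2 scale.

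The effect of high-fat diet in control rats was compared between CHFD (n = 5) and CND (n = 6). The largest increases were in Retnla and Retnlb, neighbouring genes for secreted resistin-like proteins, and in Itln1, which encodes a lectin that binds microbial glycans. Retnla (probe ILMN_1362534, GRCr8 chromosome 11, 65424685 to 65426484) rose from 5.47 ± 0.85 (SD) to 12.99 ± 0.73, a log2 difference of 7.50 (SE 0.61, adjusted p = 2.2e-08). It was detected on 5 of the 6 CND arrays, so the size of its increase depends on the background correction. Retnlb (ILMN_1365931, chromosome 11, 65446433 to 65448319), a goblet cell product, rose from 4.51 ± 0.21 to 11.53 ± 1.02 (adjusted p = 8.59e-09). Retnlb was detected on 0 of the 6 CND arrays, so it was at least 102-fold higher after background correction. Without background correction the log2 difference was 6.001 for Retnla and 4.95 for Retnlb. Itln1 (ILMN_1349778, chromosome 13, 86464641 to 86490655) rose 34.4-fold (15.7 to 75.5), from 8.84 ± 1.26 to 13.96 ± 0.42 (adjusted p = 4.04e-06). In each of these genes 5 of 5 CHFD samples lay above all CND samples. Retnla and Retnlb are paralogs, and cross-hybridization between their probes was not tested.

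Further increases in control rats on high-fat diet were smaller. Ubd, a ubiquitin-like modifier induced by cytokines, rose 10.2-fold (4.98 to 21.1; log2 difference 3.36, SE 0.51, adjusted p = 0.000642), and the lactonase gene Pon3 rose 3.87-fold (2.81 to 5.34; adjusted p = 1.24e-05), each above all CND samples in 5 of 5 CHFD samples. Cd8a, a marker of cytotoxic T cells, rose by 2.40 (SE 0.48, adjusted p = 0.00784; 0.0741 without background correction), Ptprcap by 1.91 (adjusted p = 0.0032) and Cd7 by 1.84 (adjusted p = 0.00262). The class II genes RT1-Da and RT1-Db1 each rose by 1.91 (adjusted p = 0.0049 and 0.00784). The protease inhibitor gene Slpi rose by 2.38 (adjusted p = 0.0215) and the chemokine gene Ccl5 by 2.28 (adjusted p = 0.0253). Slpi missed the threshold without CHFD 10B (adjusted p = 0.0522), CHFD 22B (0.071), CHFD 8B (0.0555) or CND 18A (0.0617). Ccl5 missed it without CHFD 8B (0.0589), CND 14A (0.0591), CND 18A (0.0781) or CND 20A (0.0519).

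The largest decrease with a gene name was in the water channel gene Aqp8 (ILMN_1367107, chromosome 1, 187424314 to 187430243), which went from 10.61 ± 1.19 in CND to 6.75 ± 1.74 in CHFD, a log2 difference of -3.87 (SE 0.70, adjusted p = 0.0041), with 4 of 5 CHFD samples below all CND samples. The retinoid carrier genes Rbp2 (-1.73, SE 0.28, adjusted p = 0.000998) and Rbp7 (-1.48, SE 0.21, adjusted p = 0.000406) fell, each lower in 5 of 5 samples. The urea transporter gene Slc14a2 was detected on 0 CHFD arrays and was at least 2.23-fold lower (adjusted p = 0.000642), while without background correction the log2 differences of Slc14a2 and Aqp8 were -0.57 and -2.99. Sorcs2, a sorting receptor gene, fell by 1.24 (adjusted p = 0.00246) and Agmat, which encodes agmatinase, by 1.03 (adjusted p = 0.00499). The epithelial cytokine gene Il18 fell by 1.31 (adjusted p = 0.0177) but missed the threshold without CHFD 28B (adjusted p = 0.0542) or CHFD 8B (0.0703), and the calcineurin-like gene Chp1 fell by 1.30 (adjusted p = 0.0145) but missed it without CHFD 8B (0.0589) and under median scaling (0.051). A probe without a gene name, ILMN_1368735, fell by 6.10 (SE 0.50, adjusted p = 2.2e-08), from 11.23 ± 1.13 to 5.14 ± 0.43.

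Besides Il18 and Chp1, 4 of the larger decreases in control rats depended on single samples. They were Cyp2d5 (-1.55, adjusted p = 0.0215), Usp2 (-1.47, adjusted p = 0.0327), Ces1d (-1.38, adjusted p = 0.0253) and Maf (-1.37, adjusted p = 0.0339). Cyp2d5 missed the threshold without CHFD 28B (adjusted p = 0.0692), CHFD 8B (0.0664) or CND 20A (0.0512) and with only the 2 groups (0.0511). Usp2 missed it without CHFD 10B (0.0756), CHFD 22B (0.0624), CHFD 28B (0.0916), CHFD 8B (0.0642) or CND 32B (0.0521), and without background correction (0.0841). Ces1d missed it without CHFD 4A (0.0699), CHFD 22B (0.0722), CND 14A (0.0733), CND 18A (0.0613) or CND 36B (0.0596), and without a filter (0.0539). Maf missed it without CHFD 4A (0.0752), CHFD 28B (0.111), CHFD 8B (0.0734), CND 14A (0.0937), CND 20A (0.082), CND 36B (0.0776), CND 38B (0.0718), RHFD 21B (0.0511) or RHFD 3A (0.0535), and with only the 2 groups (0.128). Without background correction the log2 difference was -0.94 for Usp2 and -0.74 for Ces1d. Usp2, Ces1d and Maf were also lost under other alternatives.

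In all, 132 probes passed the threshold in control rats, 98 higher and 34 lower on high-fat diet. Scaling the arrays to equal medians, which moved the median of all probes by -0.10, left 75 probes, 38 higher and 37 lower. Without CHFD 8B 83 probes passed, and without CND 18A 80. On chip 1 alone 145 probes passed and on chip 2 alone 5. Retnla differed by 7.44 on chip 1 and 7.25 on chip 2, and Retnlb by 7.07 and 6.46. Retnlb was not above background in CND, so the size of its differences depends on the background correction. Itln1 differed by 5.11 and 4.91, and Aqp8 by -4.74 and -3.19.

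Markers of T and natural killer cells (13 genes, among them Cd8a, Cd3d and Nkg7) were higher on high-fat diet in control rats, with a median log2 difference of 1.23 and a mean of 1.34 (adjusted p = 4.47e-17; 0.0123 with an estimated correlation). Of these genes 13 passed adjusted over the list alone and 6 over all genes. Macrophage and dendritic cell markers (7 genes, among them Fcer1g, Cd14, Aif1 and C1qa) were higher by a median of 1.30 (adjusted p = 1.31e-16; 0.000239 with an estimated correlation), and 7 passed adjusted over the list alone and 5 over all genes. The class II list (9 genes, median 0.80, adjusted p = 3.38e-06; 0.014 with an estimated correlation) included RT1-Ba at 1.83 and Cd74 at 1.65, and 6 of its genes passed adjusted over the list alone, 5 higher and 1 lower, and 4 over all genes. The list of B and plasma cells (5 genes, median 0.77, adjusted p = 0.0127; 0.0366 with an estimated correlation) was higher, with 2 genes adjusted over the list alone and 1 over all genes. For each of these lists the score of 5 of 5 CHFD samples lay above all CND samples. The epithelial list (Epcam, Cdh1, keratins and others) had a median of 0.03 (adjusted p = 0.81). The mean of the T and natural killer list was 1.87 on chip 1 and 0.70 on chip 2, that of the macrophage list 1.58 and 0.90, and that of the B and plasma cell list 0.37 (adjusted p = 0.263) and 0.64.

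Antimicrobial defence genes (12 genes, median 0.79, mean 1.55) were higher in control rats on high-fat diet in 5 of 5 samples (adjusted p = 3.04e-10; 7.62e-11 with an estimated correlation), with 5 genes adjusted over the list alone and 2 over all genes. Retnlb and Itln1 carried most of this, and without them the mean was 0.65 (adjusted p = 0.0487). Genes of cholesterol synthesis (17 genes, median -0.40) were lower, with 3 of 5 samples below all CND samples (adjusted p = 2.26e-06; 0.0253 with an estimated correlation). Of these 7 passed adjusted over the list alone and 0 over all genes in limma, among them Dhcr7 (-0.67), Sc5d (-0.71), Fdft1 (-0.58) and Tm7sf2 (-0.72), which encode enzymes of the pathway. The mean of the list was -0.27 on chip 1 (adjusted p = 0.172) and -0.45 on chip 2. The proliferation list (22 genes, median -0.36) was lower, with 3 of 5 samples below all CND samples (adjusted p = 0.000459; adjusted p = 0.442 with an estimated correlation), and its call ended without CHFD 22B (mean -0.20, adjusted p = 0.0731) and on chip 2 (mean -0.14, adjusted p = 0.227; chip 1, -0.40). Markers of mast cells and granulocytes were higher by a median of 0.36 in 5 of 5 samples (adjusted p = 0.000192, or 0.0771 with an estimated correlation). Their mean was 0.39 on chip 1 (adjusted p = 0.283) and 0.76 on chip 2. The goblet cell list had a median of -0.07 but a mean of 0.66 and a test for an increase (adjusted p = 0.0374; adjusted p = 0.348 with an estimated correlation), and its mean was 0.0798 without Retnlb and Itln1 (adjusted p = 0.877). The goblet call also ended without CHFD 28B (adjusted p = 0.101), CHFD 8B (0.0657), CND 32B (0.117), CND 38B (0.0934) or RND 17B (0.0529). Of the 35 lists 12 were called in control rats.

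**Figure D1:**
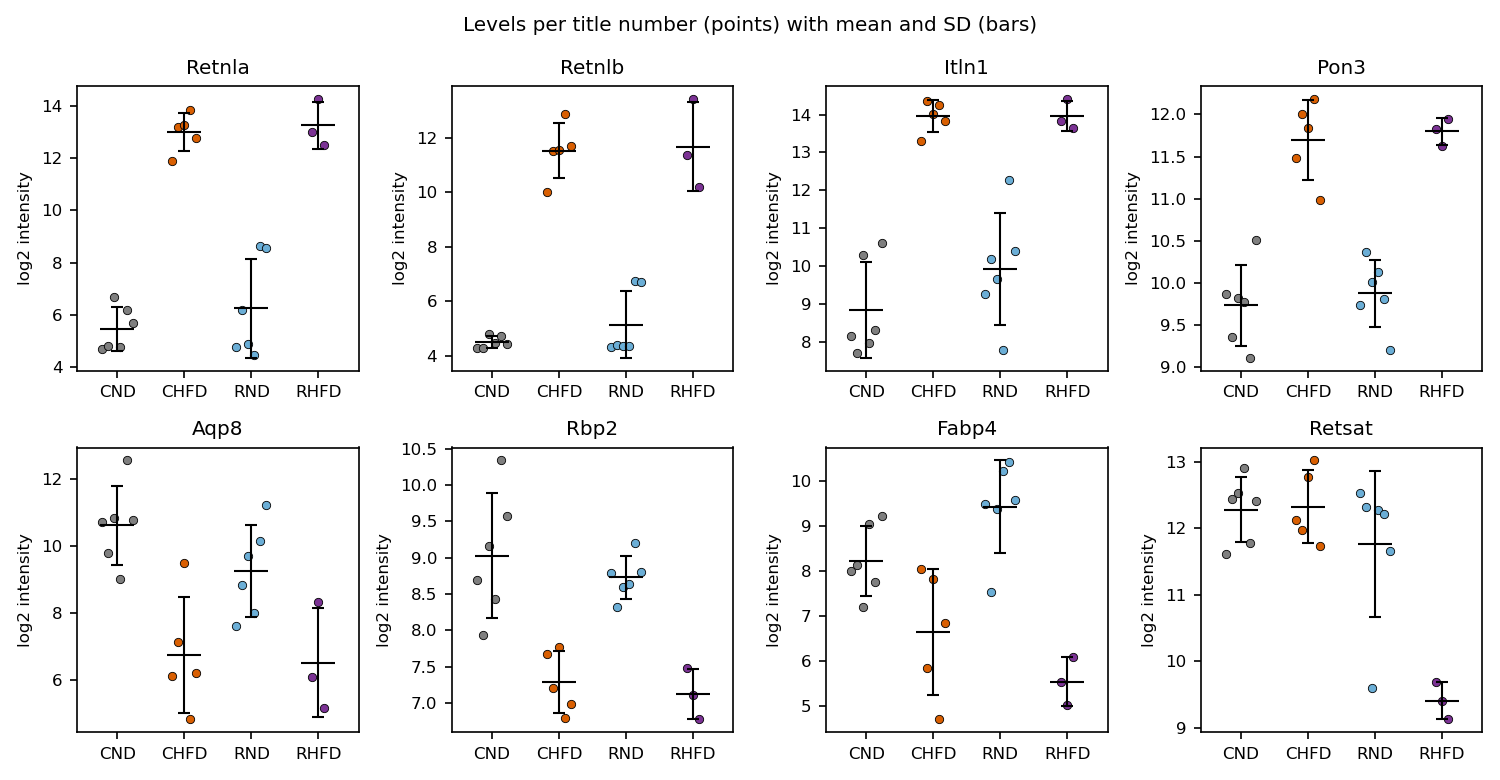
Log2 intensity of Retnla, Retnlb, Itln1, Pon3, Aqp8, Rbp2, Fabp4 and Retsat in each sample (points) of the 4 groups, with the mean and SD (bars). Retnla lies at 12.99 in CHFD and 13.25 in RHFD, against 5.47 in CND and 6.25 in RND.

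The effect of high-fat diet in IUGR rats was compared between RHFD (n = 3) and RND (n = 6). The same 3 genes had the largest increases: Retnla rose from 6.25 ± 1.90 to 13.25 ± 0.92, a log2 difference of 7.004 (SE 0.69, adjusted p = 1.64e-06), Retnlb from 5.15 ± 1.22 to 11.67 ± 1.63, a log2 difference of 6.51 (SE 0.59, adjusted p = 5.72e-07), and Itln1 from 9.93 ± 1.47 to 13.97 ± 0.40, or 16.5-fold (6.75 to 40.2; adjusted p = 0.00139). Retnla was detected on 4 and Retnlb on 2 of the 6 RND arrays. The log2 difference of Retnlb ran from 4.86 to 7.34 over the alternatives, that of Retnla from 5.76 to 7.94. Pon3 rose 3.79-fold (adjusted p = 0.000214). Retnla and Retnlb lay above all RND samples in 3 of 3 RHFD samples. Chgb, which encodes a granin of endocrine cells, rose 3.89-fold (2.23 to 6.79; adjusted p = 0.0112), from 9.98 ± 0.68 to 11.94 ± 0.68. The tuft cell marker Dclk1 rose by 1.62 (SE 0.30, adjusted p = 0.00812), and Nts, which encodes the gut peptide neurotensin, was at least 2.47-fold higher (adjusted p = 0.00666; log2 difference 0.64 without background correction). Apoe, which encodes a lipid carrier of macrophages, rose by 1.56 (adjusted p = 0.00874), and Ubd by 2.51 (adjusted p = 0.0325; 0.0655 without background correction).

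Fabp4, the fatty acid binding protein of adipocytes and macrophages (ILMN_1376344, chromosome 2, 93488251 to 93492961), had the largest decrease with a gene name in IUGR rats, from 9.43 ± 1.02 to 5.55 ± 0.53, a log2 difference of -3.88 (SE 0.55, adjusted p = 0.000439), below all RND samples in 3 of 3, and of -2.63 without background correction. Retsat (ILMN_1356474, chromosome 4, 106211459 to 106220222), which encodes retinol saturase, fell from 11.76 ± 1.10 to 9.41 ± 0.28 (log2 difference -2.35, SE 0.42, adjusted p = 0.00636), below all RND samples in 2 of 3. The class I gene RT1-S2 (ILMN_1368215, chromosome 20, 2655054 to 2664895) fell from 8.82 ± 0.26 to 6.51 ± 0.39 (log2 difference -2.31, SE 0.53, adjusted p = 0.0324; 0.0636 without background correction), in 3 of 3. Rbp2 fell by 1.61 (SE 0.31, adjusted p = 0.0103), the nuclease gene Dnase1 by 2.01 (adjusted p = 0.00874) and the sterol reductase genes Tm7sf2 by 1.38 (adjusted p = 0.00636) and Dhcr7 by 1.04 (adjusted p = 0.0102). Slc14a2 was at least 2.11-fold lower (adjusted p = 0.00874; log2 difference -0.51 without background correction). The cytochrome gene Cyp2c24 fell by 1.26 (adjusted p = 0.00636). Aqp8 differed by -2.73 (SE 0.80) and did not pass (adjusted p = 0.121).

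Asb2 (1.83, adjusted p = 0.0349), Dnai7 (1.80, adjusted p = 0.0112; another probe -0.05) and Plcg2 (1.59, adjusted p = 0.0164) rose in IUGR rats, and Cyp2d5 (-1.92, adjusted p = 0.0164), Ace (-1.68, adjusted p = 0.0114), Cyp2d1 (-1.61, adjusted p = 0.0114) and Maf (-1.55, adjusted p = 0.0465) fell, but each call depended on single samples. Without RHFD 25B the adjusted p was 0.0565 for Asb2, Cyp2d5 and Cyp2d1, 0.159 for Dnai7, 0.216 for Plcg2, 0.108 for Ace and 0.0918 for Maf. Without RHFD 3A it was 0.504 for Asb2, 0.0642 for Dnai7, 0.0905 for Plcg2, 0.146 for Cyp2d5, 0.185 for Ace, 0.149 for Cyp2d1 and 0.348 for Maf. Without RHFD 21B it was 0.0788 for Asb2, 0.0944 for Cyp2d5 and 0.258 for Maf, and without RND 35B 0.0756 for Asb2, 0.0503 for Plcg2 and 0.0663 for Maf. Asb2 also missed the threshold without RND 19B (0.0524), RND 37B (0.0758) or RND 39B (0.0655). Maf also missed it without CHFD 22B (0.0503), CHFD 8B (0.0532), CND 20A (0.0546), RND 17B (0.0516), RND 19B (0.0684), RND 33B (0.0747), RND 37B (0.101) or RND 39B (0.0751). Without background correction the adjusted p was 0.0636 for Asb2, 0.063 for Cyp2d5 and 0.112 for Maf, and with arrays of a title number averaged it was 0.0517 for Dnai7 and 0.0611 for Plcg2. The log2 differences without background correction were 1.13 for Dnai7, -1.10 for Ace, -1.03 for Cyp2d1 and -1.01 for Maf. Asb2, Plcg2 and Maf were also lost under other alternatives.

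In IUGR rats 90 probes passed, 57 higher and 33 lower, and under median scaling 54 passed, 28 higher and 26 lower. Chip 1 alone gave 12 probes and chip 2 alone 31, with the same 3 RHFD samples on both chips. Only 8 probes passed without RHFD 25B, 17 without RHFD 3A, 37 without RND 35B and 54 without RND 37B. Without RHFD 25B the adjusted p was 0.0555 for Retsat, Chgb, Dnase1, Tm7sf2, Dhcr7 and Cyp2c24, 0.104 for Dclk1, 0.116 for Apoe, 0.0683 for Rbp2, 0.0592 for Slc14a2, 0.146 for RT1-S2 and 0.165 for Ubd. Without RHFD 3A it was 0.0652 for Retsat, 0.211 for Chgb, 0.138 for Apoe, 0.143 for Rbp2, 0.0734 for Tm7sf2, 0.138 for Dhcr7, 0.0556 for Cyp2c24, 0.0667 for Slc14a2, 0.267 for RT1-S2 and 0.159 for Ubd. Without RHFD 21B it was 0.0788 for Nts, 0.105 for Dnase1, 0.0728 for RT1-S2 and 0.142 for Ubd. RT1-S2 and Ubd each also missed the threshold without 4 single RND samples, at adjusted p of 0.0552 (RND 17B), 0.057 (RND 19B), 0.0663 (RND 35B) and 0.0545 (RND 37B) for RT1-S2 and 0.0608 (RND 17B), 0.0592 (RND 35B), 0.0804 (RND 37B) and 0.0578 (RND 39B) for Ubd.

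The lists of T and natural killer cells, of macrophages and dendritic cells and of mast cells and granulocytes were higher in IUGR rats too. T and natural killer markers had a median of 1.10 (adjusted p = 1.22e-11; 0.0425 with an estimated correlation), with 11 of 13 genes adjusted over the list alone and 1 over all genes. Macrophage and dendritic markers had a median of 1.32 (adjusted p = 1.22e-11; 0.00505 with an estimated correlation), with 6 of 7 genes adjusted over the list alone and 3 over all genes, among them Fcer1g (1.23) and the complement gene C1qa (1.43). Without RHFD 25B or RHFD 3A the adjusted p was 0.0633 or 0.0666 for Fcer1g and 0.113 or 0.207 for C1qa. Mast cell markers had a median of 0.69 (adjusted p = 1.91e-07; 0.0115 with an estimated correlation), and 4 of 6, among them Mcpt1 and Mcpt10, passed adjusted over the list alone and 0 over all genes in limma. The class II list (median 0.20, adjusted p = 0.206), the list of B and plasma cells (median -0.19, adjusted p = 0.407) and the epithelial list (median 0.11, adjusted p = 0.159) were not called. The macrophage and mast cell scores of 3 of 3 RHFD samples and the T and natural killer scores of 2 of 3 lay above all RND samples. The mean of the T and natural killer list was 0.77 on chip 1 and 1.51 on chip 2, and that of the macrophage list 0.79 and 1.40.

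Genes of cholesterol synthesis had a median of -0.41 in IUGR rats (adjusted p = 3.99e-06; 0.0331 with an estimated correlation), with 2 genes passing adjusted over the list alone and the same number over all genes, and 2 of 3 samples below all RND samples. Genes of butyrate uptake and use, the main fuel of colonocytes, were lower (8 genes, median -0.55, adjusted p = 0.00444; 0.0319 with an estimated correlation) in 3 of 3 samples, with Bsg (-0.60), Bdh1 (-0.65) and the transporter Slc5a8 (-0.81) passing adjusted over the list alone and 0 over all genes. Antimicrobial defence genes were higher (median 0.41, mean 0.87, adjusted p = 0.000254; 0.000581 with an estimated correlation), but without Retnlb and Itln1 their mean was -0.01 (adjusted p = 0.727), and on chip 2 the mean of the list was 0.77 (adjusted p = 0.0503). Proliferation genes were lower (median -0.45, adjusted p = 3.99e-06; adjusted p = 0.3 with an estimated correlation) in 3 of 3 samples, and 8, among them Ube2c, Aurkb, Cdk1 and Cdc20, passed adjusted over the list alone and 0 over all genes. The enteroendocrine list was higher (median 0.17, mean 0.43, adjusted p = 0.00444; adjusted p = 0.147 with an estimated correlation), with 2 genes, among them Chgb, passing adjusted over the list alone and the same number over all genes, and lost its call without RHFD 3A (adjusted p = 0.067) and on chip 1 (0.0614). Immediate early and heat shock genes had a mean of 0.78 (adjusted p = 0.00093). Their adjusted p was 0.324 with an estimated correlation and 0.0541 with the title letter as a term. Without RHFD 3A the mean was 0.0559 (adjusted p = 0.863). The adipocyte list, which holds Fabp4, had a median of -0.09 and a mean of -0.81 (adjusted p = 0.0169; adjusted p = 0.148 with an estimated correlation) and was lower in 3 of 3 samples. Fabp4 and Car3 (-1.09) passed adjusted over the list alone and 1 gene over all, and the call ended without RHFD 25B (adjusted p = 0.108) or RND 17B (0.1), on chip 1 (0.111) and with the title letter as a term (0.0541). Of the 35 lists 14 were called in IUGR rats.

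The responses to diet in the 2 birth groups shared 31 higher probes (0.548 expected if independent, Fisher's exact test, two-sided, p = 1.55e-49) and 11 lower probes (0.11 expected, p = 1.72e-20). Fisher's test counts probes as independent units, and both comparisons share 1 fit with the same spread for each probe. Its p therefore does not measure replication across rats. Of the 180 probes past the threshold in either group, 173 had the same sign in both. Across these probes, which are genes and not independent replicates, Pearson's r between the log2 differences was 0.862, and across all tested probes it was 0.517, with a Spearman's rho of 0.235. A call in 1 birth group alone was not shown to be a difference: the interaction was -2.33 (SE 0.73) for Fabp4 (adjusted p = 0.972) and -2.40 (SE 0.55) for Retsat (adjusted p = 0.902).

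**Figure D2:**
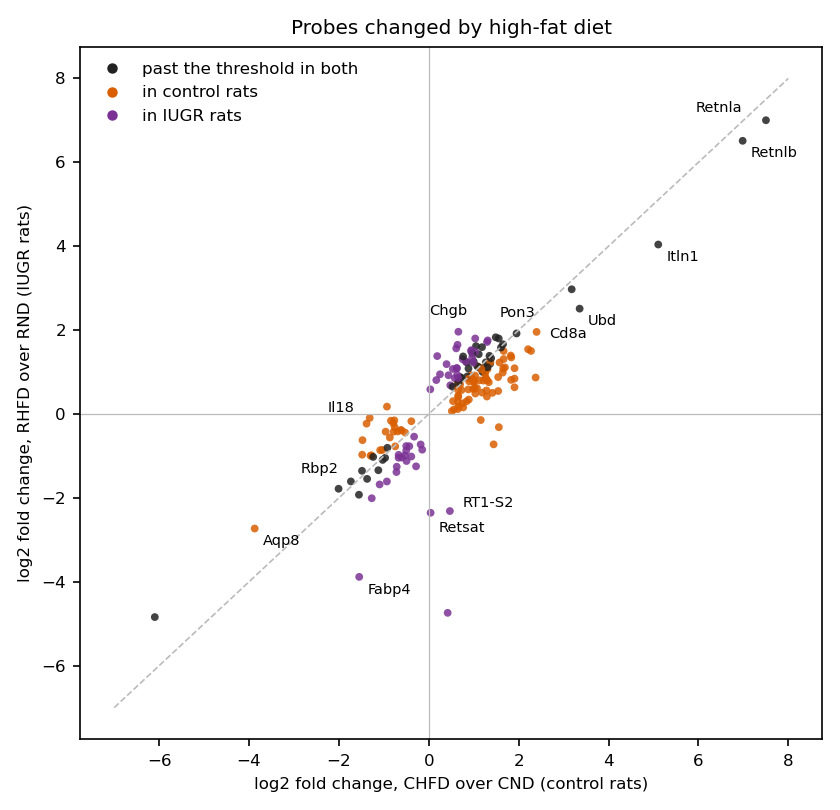
Log2 difference between high-fat diet and chow in control rats (horizontal) and in IUGR rats (vertical) for the 180 probes past the threshold in both (black), in controls (orange) or in IUGR rats (purple), with the line of equality dashed. Of these probes 173 have the same sign in both groups.

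Averaged over birth status, the diet comparison set 8 samples on high-fat diet against 12 on chow. Most samples on chow were near background for Retnlb, so the size of its change depends on the background correction. Retnla rose by 7.25 (SE 0.46, adjusted p = 1.32e-10), Retnlb by 6.75 (SE 0.39, adjusted p = 3.73e-11), Itln1 by 4.57 (SE 0.42, adjusted p = 1.12e-07), Ubd by 2.93 (adjusted p = 3.38e-05), Pon3 by 1.94 (SE 0.17, adjusted p = 7.32e-08), Cd8a by 2.18 (SE 0.36, adjusted p = 0.000489) and the T cell receptor gene Cd3d by 1.61 (SE 0.30, adjusted p = 0.00141). Reg4, a secreted lectin, rose by 1.88 (SE 0.46, adjusted p = 0.0156; 0.111 without RHFD 21B). Ccl5 rose by 1.89 (adjusted p = 0.00515), Asb2 by 1.66 (adjusted p = 0.000577) and Slpi by 1.62 (adjusted p = 0.0196; 0.0601 without RHFD 25B and 0.0955 without RHFD 3A), and Nts was at least 2.38-fold higher (adjusted p = 1.29e-05). Aqp8 fell by 3.30 (SE 0.53, adjusted p = 0.000356), Fabp4 by 2.72 (SE 0.36, adjusted p = 4.66e-05) and Rbp2 by 1.67 (adjusted p = 2.15e-05). The goblet cell inhibitor gene Spink4 fell by 2.22 (SE 0.49, adjusted p = 0.00691; 0.0535 without RHFD 25B), the aspartic protease gene Napsa by 1.82 (adjusted p = 0.00468) and the arginase gene Arg2 by 1.39 (adjusted p = 0.00793). Cyp2d5 fell by 1.74 (adjusted p = 0.000213), Ccn3 by 1.69 (adjusted p = 0.0103; 0.0519 without RHFD 21B and 0.0693 without RHFD 3A), Dnase1 by 1.64 (adjusted p = 0.00022), Maf by 1.46 (adjusted p = 0.000691) and Ace by 1.39 (adjusted p = 0.000356), and Slc14a2 was at least 2.17-fold lower (adjusted p = 1.29e-05). Without background correction the log2 differences of Nts, Slc14a2 and Ace were 0.64, -0.54 and -0.91. The desaturase gene Scd fell by 1.25 (adjusted p = 0.00116), Tm7sf2 by 1.05 (adjusted p = 0.000267) and Dhcr7 by 0.86 (adjusted p = 0.000268). The clock regulator Nfil3 rose by 1.07 (adjusted p = 0.000229), the cytokine gene Il1b by 0.82 (adjusted p = 0.00134) and the granzyme gene Gzma by 1.58 (adjusted p = 0.00163).

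Here 436 probes passed, 259 higher and 177 lower, and under median scaling 379, 155 higher and 224 lower. The count was 282 without RHFD 21B and 246 without RHFD 3A, and the chips alone gave 126 and 132 probes. Of the 35 lists 19 were called, and 5 held with an estimated correlation: T and natural killer markers (mean 1.24, adjusted p = 2.3e-19; 0.00531 with an estimated correlation; 13 genes adjusted over the list alone, 12 over all), macrophage markers (mean 1.15, adjusted p = 4.24e-19; 5.25e-05; 7 and 7), mast cell markers (mean 0.72, adjusted p = 4.81e-08; 0.00531; 5 and 4), antimicrobial defence (mean 1.21, adjusted p = 4.76e-09; 1.6e-09; 6 and 3) and cholesterol synthesis (mean -0.39, adjusted p = 2.2e-08; 0.00531; 11 and 4). The antimicrobial call ended without Retnlb and Itln1 (mean 0.32, adjusted p = 0.177). Proliferation genes were lower, with a mean of -0.41 (adjusted p = 7.44e-07; adjusted p = 0.2 with an estimated correlation), and 11 passed adjusted over the list alone and 3 over all genes, among them Ube2c (-1.14). Without CND 32B 12 lists were called.

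**Figure D3:**
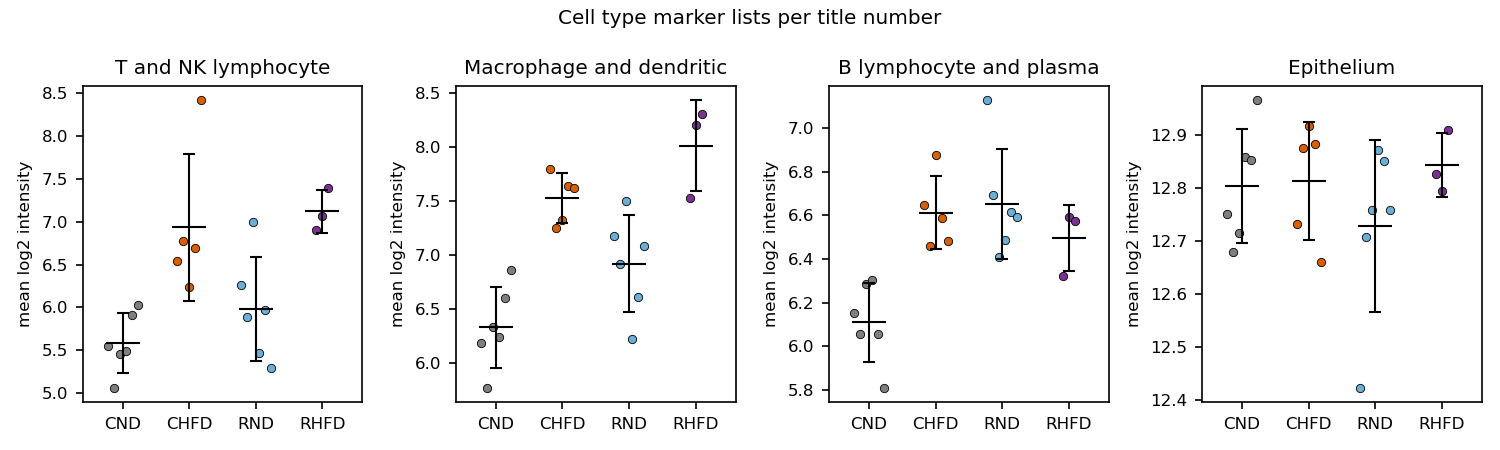
Mean log2 intensity of the markers of T and natural killer cells, macrophages and dendritic cells, B and plasma cells and epithelium in each sample (points) by group, with the mean and SD (bars). The T and natural killer score of CHFD 8B is 8.42, against 6.24 to 6.78 in the other CHFD samples and 5.06 to 6.03 in CND.

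The effect of IUGR on chow was compared between RND (n = 6) and CND (n = 6). The smallest p was that of Acot5, an acyl-CoA thioesterase gene, with a log2 difference of 1.01 (SE 0.18) and 6 of 6 RND samples above all CND samples, which did not pass (adjusted p = 0.0592). Mrpl50, a mitochondrial ribosomal protein gene (0.97, adjusted p = 0.174), Rgs10 (0.83, adjusted p = 0.174), RT1-S2 (2.11, SE 0.44, adjusted p = 0.174) and the class II chaperone gene RT1-DMb (1.04, adjusted p = 0.197) were higher without passing. Akap9 (-0.89, adjusted p = 0.174), Rnf138 (-0.82), Mtf2 (-0.91), Luc7l3 (-0.91) and Alg11 (-0.48) were lower without passing. In limma 0 probes passed and 1235 had an unadjusted p under 0.05, against 509.65 expected by chance. Without CHFD 4A 2 probes passed, without CND 38B 3, and without RND 35B or RND 39B 1.

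Of 9 lists called in IUGR rats on chow, the list of B and plasma cells held with an estimated correlation. Its genes were higher by a median of 0.65 (adjusted p = 0.00461; 0.0401 with an estimated correlation), with Cd79b (0.80), Blnk (1.11) and Cd37 (0.65) passing adjusted over the list alone and 0 over all genes, and the score of 6 of 6 RND samples lay above all CND samples. Its mean was 0.58 on chip 1 (adjusted p = 0.0633) and 0.51 on chip 2 (0.0527). Macrophage markers (median 0.54, adjusted p = 0.00042; adjusted p = 0.317 with an estimated correlation) and the class II list (median 0.82, adjusted p = 0.00071; adjusted p = 0.176 with an estimated correlation) were higher, each with 5 genes adjusted over the list alone and 0 over all. Their means were 1.11 and 1.07 on chip 1 and 0.07 and 0.15 on chip 2, chips that in CND hold samples with different title letters. The T and natural killer list had a mean of 0.40 (adjusted p = 0.0348; adjusted p = 0.652 with an estimated correlation), 1.03 on chip 1 and -0.23 on chip 2, and its call ended without CND 14A (0.052), CND 18A (0.208), CND 20A (0.0668), CND 32B (0.0754), RND 17B (0.0624), RND 33B (0.327) or RND 37B (0.0679). Without RND 17B 5 lists were called.

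On high-fat diet, IUGR rats (RHFD, n = 3) were compared with controls (CHFD, n = 5). An unadjusted p under 0.05 was seen for 106 probes, against 509.65 expected by chance. Retsat was lower in 3 of 3 RHFD samples than in all CHFD samples, at 9.41 ± 0.28 against 12.32 ± 0.55. Its log2 difference was -2.91 (SE 0.43, adjusted p = 0.00448), and Retsat was the 1 probe that passed. It missed the threshold without RHFD 25B (adjusted p = 0.0998) or RHFD 3A (0.092), and on chip 1 alone the difference was -2.91 (adjusted p = 0.994). Retsat also missed the threshold with arrays of a title number averaged, and it passed on chip 2 alone. Without CHFD 28B 3 probes passed, and without RHFD 21B or RND 39B 2. The transcriptional corepressor gene Nab1 differed by -2.12 (SE 0.42) and did not pass (adjusted p = 0.179). Apoe (1.07), the aldo-keto reductase genes Akr1c12 (1.45), Akr1c12l1 (1.497) and Akr1c13 (1.62), Itprid1 (0.59), Tlr2 (-1.005), Gclc (-0.91), Pmm2 (-1.003) and the oxidase gene Duox2 (-1.22) did not pass (adjusted p = 1). Macrophage markers were higher, with a median of 0.58 (adjusted p = 4.41e-06; adjusted p = 0.268 with an estimated correlation), in 2 of 3 samples above all CHFD samples, and 0 passed adjusted over the list alone or over all genes in limma.

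Averaged over diet, 433 probes had an unadjusted p under 0.05 between IUGR rats and controls, against 509.65 expected by chance. Retsat differed by -1.71 (SE 0.28, adjusted p = 0.0195) and was the 1 probe that passed. Its level was low in RHFD (9.12 to 9.69) and RND 33B (9.59). The other RND samples (11.65 to 12.52) lay within the CND range (11.61 to 12.91), so the Retsat average came mostly from high-fat diet. The Retsat call ended under median scaling (adjusted p = 0.278) and without CHFD 10B (0.0598), CHFD 22B (0.0626), CND 20A (0.0507), RHFD 25B (0.176) or RHFD 3A (0.21). That call also ended on each chip alone, without background correction, with series matrix values and with arrays of a title number averaged. Without CHFD 28B, RHFD 21B or RND 39B, 2 probes passed. Acot5 (0.61), Mrpl50 (0.70), Ggact (0.99), R3hdm4 (0.45), Asb3 (-0.72), Vwa7 (-0.35), Nab1 (-1.19) and Gclc (-0.88), which encodes a subunit of the enzyme that starts glutathione synthesis, did not pass (adjusted p = 0.361), nor did Rgs10 (0.58, adjusted p = 0.377) and Rnf138 (-0.53, adjusted p = 0.694). Macrophage markers were higher by a median of 0.56 (adjusted p = 2.12e-09; 0.0335 with an estimated correlation), with 6 of 7 genes, among them C1qa (0.61), C1qb (0.80) and C1qc (0.80), passing adjusted over the list alone and 0 over all genes, and the adjusted p was 0.0934 on chip 2 and 0.123 with fry. Of the 35 lists 6 were called, and 11 without CHFD 22B.

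The interaction asked whether the diet response differed with birth status. In limma 0 probes passed and 413 had an unadjusted p under 0.05, against 509.65 expected by chance. The smallest p belonged to Retsat (-2.40, SE 0.55) and Vps52 (-1.44), at an adjusted p of 0.902. RT1-S2 (-2.78), RT1-A1 (-2.22), Luc7l3 (1.30), Akap9 (1.11), Cenpc (0.96), Abca1 (0.90) and Klf9 (1.02) did not pass either (adjusted p = 0.972). Without CND 38B 3 probes passed, and without CHFD 28B or RND 33B 1. The list of B and plasma cells had a smaller diet response in IUGR rats, with a median of -0.55 and a mean of -0.66 (adjusted p = 0.00547; 0.0182 with an estimated correlation), and Cd79b (-1.49) passed adjusted over the list alone and 0 genes over all. The interferon list (mean -0.30, adjusted p = 0.0273; adjusted p = 0.672 with an estimated correlation) and the class II list (mean -0.54, adjusted p = 0.0273; adjusted p = 0.4933 with an estimated correlation) were called as well. The mean was -0.50 on chip 1 and -0.0393 on chip 2 (adjusted p = 0.784) for the interferon list and -1.03 and -0.10 (0.846) for the class II list, and with the title letter as a term the adjusted p was 0.171 and 0.201. The B and plasma cell list was -0.67 on chip 1 (adjusted p = 0.0889) and -0.66 on chip 2. With fry, adjusted p was 0.767 for the interferon list, 0.725 for the class II list and 0.11 for the list of B and plasma cells. The interferon call ended without CHFD 4A (0.127), CHFD 28B (0.0544), CHFD 8B (0.0542), CND 18A (0.0901), CND 20A (0.114), RHFD 25B (0.233), RND 33B (0.0679) or RND 37B (0.124). The class II call ended without CHFD 10B (0.0545), CHFD 22B (0.116), CND 18A (0.077), CND 20A (0.0511), RHFD 21B (0.238), RND 17B (0.0898), RND 33B (0.0686) or RND 37B (0.0859), and 1 list was called without CND 18A, CND 20A, RND 33B or RND 37B.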

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

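The tests of the T and B cell lists against each other, of wrong or swapped labels and of other splits for the probe counts, and the look at ILMN_1650140, RT1-A1 and the neighbours of Retsat, were chosen only after the result was seen. Among 459 pairs of a gene and a group, 32 had a sample far from the others of its group, and chance flags about 1 in 20 groups, or 22.95 pairs.

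In control rats on high-fat diet, CHFD 8B stood apart in Cd8a (9.66), Ccl5 (12.82), Ptprcap (9.90) and Cd3d (8.95), all genes of lymphocytes. RT1-S2 stood apart in CND 38B (9.79) and Retsat in RND 33B (9.59). RND 17B stood apart in Tm7sf2 (8.96), Bsg (10.62), Acot1 (5.97), Prom1 (11.73), Dgat1 (10.59) and R3hdm4 (9.53). Of all samples, RND 17B also had the lowest epithelial (12.42) and enteroendocrine (6.41) scores and the highest score of B and plasma cells (7.13). CND 18A stood apart in RT1-Da (7.76) and Txnrd1 (8.07), CHFD 22B in Limk1 (4.81) and Fcer1g (8.44), CND 20A in Me1 (8.57) and Akr1c12 (8.21), and RND 35B in Cd74 (6.11), Rgs10 (4.84) and C1qb (5.25). CND 32B stood apart in Nlrp6 (9.12), Mtf2 (6.29) and Cpt2 (11.08), CND 36B in Sgk1 (13.27) and Atf4 (9.92), and CHFD 4A in Cbr1 (10.48) and Scg3 (5.59). Single genes stood apart in RND 19B (Fabp4, 7.53), RND 33B (Tyrobp, 5.59), RND 39B (Nab1, 6.71) and CHFD 10B (Acly, 8.04). The interaction of diet and birth status passed the preset test in the interferon list (-0.30; adjusted p = 0.672 with an estimated correlation), the class II list (-0.54; 0.4933) and the list of B and plasma cells (-0.66; 0.0182). None of these passed with fry, and the splits of the samples do not exclude chance for them.

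Leukocyte transcripts were higher on high-fat diet. A lower epithelial share in the preparations, with the mix of leukocytes unchanged, would raise the markers of all leukocytes. The log2 rise would be alike only for markers well above background. Averaged over birth status, T and natural killer markers rose by 1.24 and those of B and plasma cells by 0.17. That is a difference of 1.07 (permutation test, two-sided, p = 0.00225). The B and plasma cell score rose by 0.50 in control rats and changed by -0.16 in IUGR rats. The difference between the lists was 1.30 in IUGR rats (exact permutation test, two-sided, p = 0.0357) and 0.85 in control rats (exact p = 0.0606). Without CHFD 8B it was 0.44 in control rats (exact p = 0.148). This pair of lists was chosen after the result was seen, and p was not adjusted. Only 5 genes of B and plasma cells were tested. A lower epithelial share alone, with an unchanged mix of leukocytes, is therefore argued against only weakly in IUGR rats and may hold in control rats. A lower share together with a changed mix of leukocytes stays open in both, since these lists cannot tell them apart. CHFD 8B alone was not the source, since without it the T and natural killer list still had a mean of 0.99 in control rats (adjusted p = 7.64e-13), and lymphoid follicle tissue in CHFD 8B is argued against by its B cell score, -0.40 relative to the highest other CHFD sample. More T cells and macrophages in the epithelium on high-fat diet, or more of them released with the epithelial cells, may also remain, and neither was tested.

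RT1-S2 was high in all RND samples (8.48 to 9.23), in CND 38B (9.79) and in CHFD 4A (9.09). ILMN_1650140, a probe without a gene name, followed the same samples, at 9.59 to 10.11 in RND, 10.32 in CND 38B and 10.52 in CHFD 4A. It lay at 4.63 to 5.43 in all others. RT1-A1 was 11.69 to 12.91 in RND, 12.75 in CND 38B and 11.96 in CHFD 4A, but also 12.32 in CHFD 28B. In the remaining samples RT1-A1 lay between 9.58 and 10.98. CHFD 4A as a mislabelled RND sample is argued against by its Retnlb level (highest on chow minus CHFD 4A, -4.78). A swap of CND 38B with an RND sample would leave a low RT1-S2 value in RND, but the lowest RND sample lay 1.82 above the other CND samples. That check used the same values that showed the pattern, so it is not independent of it. An inherited segment around RT1-S2 may be shared by these samples. RT1 genes were left out of this check, so it says nothing about the other members of that family. Of the remaining genes, 0 of the 50 that covary most with RT1-S2 within groups lie within 100 genes of it. Only 0.13 were expected, so a count of 0 decides nothing whatever threshold was set for it. Birth status alone is argued against by the low RHFD samples (6.17 to 6.93), while a single wrong label of CND 38B and a difference limited to the probe target stay open. RT1-A1 and ILMN_1650140 followed nearly the same samples, but whether their probes share sequence with that of RT1-S2 was not tested.

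Retsat was low in RHFD (9.12 to 9.69) and in RND 33B (9.59) and lay between 11.61 and 13.02 in the other samples. A swapped label of RND 33B is argued against by its Retnlb level, -5.62 relative to the lowest value on high-fat diet. An inherited segment around Retsat may be involved and stays open: 1 of the 50 genes that covary most with it within groups lies within 100 genes of it (0.273 expected, one-sided exact hypergeometric test, p = 0.24), too few to decide, although a p of this size had been set to count against a segment. Its neighbours Capg, Thnsl2, Wbp1, Dok1 and Cd8a ranked 15, 78, 96, 97 and 100 of 7333 genes, 40 of which lie in this window. Pearson's r with Retsat was 0.66, 0.57 and 0.56 for Capg, Thnsl2 and Wbp1 and -0.56 for Dok1 and Cd8a. These ranks were not tested. Diet alone is argued against by CHFD (11.72 to 13.02) and birth status alone by 5 of 6 RND samples (11.65 to 12.52), while their combination and a difference limited to the probe target stay open.

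Other splits of the samples into groups of the same sizes were fitted in the same way, and chance is taken as excluded where under 5% of the splits gave as much, a share not adjusted over the 14 counts. By this limit chance is excluded for the probes changed by diet in IUGR rats (1 of 84 splits as large, the real one included, with 90 probes, highest other 5). The same holds for the probes changed by diet on average (1 of 100, with 436 probes, highest other 229) and for the lists on average (1 of 100, with 19 lists, highest other 15). The probes changed by diet in controls came under 5% too (2 of 100, with 132 probes, highest other 203). The lists in controls (4 of 100, with 12 lists, highest other 17) and in IUGR rats (3 of 84, with 14 lists, highest other 15) also came under 5%, but barely. The median of the other splits was 6 lists in controls and 4 in IUGR rats. In controls the splits were drawn from 462 possible ones. Shares of 4 of 100 for the lists and 2 of 100 for the probes are thus uncertain. Chance is not firmly excluded for the lists or the probes in controls. Among these, another split gave more than the real one for the probes in controls and for the lists in controls and in IUGR rats. Chance cannot be excluded for the probes changed by IUGR on high-fat diet (7 of 56; 1, highest other 202) and on average (9 of 100; 1, highest other 4). For IUGR on chow and the interaction the real count was 0, which 100 of 100 splits must reach, so the splits decide nothing there (highest other 7 and 2). Chance cannot be excluded for the lists on chow (9 of 100; 9, highest other 15), on high-fat diet (49 of 56; 2, highest other 14), on average (41 of 100; 6, highest other 12) and for the interaction (81 of 100; 3, highest other 15). The split with 202 probes set CHFD 4A, CHFD 22B and RHFD 3A against the other samples on high-fat diet, which points to a structure of the samples that the groups do not describe.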

How the results depend on the processing

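Leaving Retnlb and Itln1 out of the lists was chosen only after the result was seen. Of 148 named gene results past the threshold 0 reversed, and 119 still passed under median scaling, 129 without background correction, 65 on chip 1 and 46 on chip 2. Probe counts are given here in the order diet in controls, diet in IUGR rats, IUGR on chow, IUGR on high-fat diet, diet average, IUGR average and interaction. Leaving out 1 sample gave 80 to 198, 8 to 110, 0 to 3, 0 to 3, 246 to 536, 0 to 2 and 0 to 3 probes, and 9 to 15, 11 to 18, 5 to 10, 1 to 4, 12 to 19, 4 to 11 and 1 to 4 lists. Diet in controls gave 75 probes under median scaling, 57 with probes detected on all arrays, 5 on chip 2 and 250 with arrays independent, and 6 lists on chip 1 and with an estimated correlation. Diet in IUGR rats gave 57 probes without background correction and with series matrix values, 54 under median scaling, 33 with probes detected on all arrays, 12 on chip 1, 31 on chip 2, 318 with arrays independent, 43 with shared title numbers averaged, 302 with array weights and 151 with only the compared groups, and 6 lists with an estimated correlation and with fry. IUGR on chow gave 3 probes under median scaling and on chip 1, 2 without a filter, 1 without a chip term, with arrays independent and with averaging, and 49 with array weights; lists numbered 4 on chip 1, 5 on chip 2 and with the title letter, and 1 with an estimated correlation and with fry. IUGR on high-fat diet gave 0 probes on chip 1 and with averaging, 3 with arrays independent and with array weights and 2 with only the compared groups; lists numbered 1 without a chip term, with arrays independent, with averaging and with only the compared groups, 5 on chip 1, and 0 with an estimated correlation and with fry. The diet average gave 196 probes with probes detected on all arrays, 126 on chip 1, 132 on chip 2, 742 with arrays independent and 675 with array weights, and 5 lists with an estimated correlation. The IUGR average gave 0 probes without background correction, under median scaling, with series matrix values, on chip 2 and with averaging, 3 without a filter, 2 on chip 1 and 4 with array weights, and 1 list with an estimated correlation and 0 with fry. The interaction gave 2 probes on chip 1 and 1 with array weights; lists numbered 6 under median scaling, on chip 1 and with array weights, 1 with arrays independent, with averaging and with an estimated correlation, and 0 with fry. Lists that reversed were goblet cells in controls without Retnlb and Itln1 (mean 0.0798, with the test turned), interferon on chip 2 for diet in controls (-0.0851) and for IUGR on chow (0.0195, with the test turned), immediate early genes for IUGR on chow with the title letter (0.21), T and natural killer cells for IUGR on chow on chip 2 (-0.23) and ribosomal proteins for the IUGR average on chip 1 (-0.0614). Single chips hold 3 arrays per group and filters test fewer probes; for the other changes the cause was not tested. With only CND and CHFD, or CND and RND, in the fit, arrays were treated as independent. No paired analysis was possible because no title number occurs in more than 1 group. List counts under other filters were not planned. Transcripts near background, such as Retnlb in CND, give lower bounds of a change that hold only for the group means after background correction.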

Other observations

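The adjusted p here come from the planned comparisons, no other tests were run, and the samples and probes were picked after their values were seen. On chow, RND 37B and RND 39B had Retnlb levels of 6.75 and 6.71, against 4.30 to 4.80 in the other samples on chow, and Retnla levels of 8.63 and 8.54. The mean level of the immediate early and heat shock genes was 11.32 in CHFD 4A, 11.02 in RHFD 3A and 10.15 in CND 14A. It lay between 8.69 and 9.39 in all other samples.

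Some of the largest differences between the diets were in probes without a gene name. ILMN_1368735 fell by 6.10 (adjusted p = 2.2e-08) in control rats and by 4.84 (adjusted p = 2.89e-05) in IUGR rats. ILMN_1369184 rose by 3.18 and 2.97. ILMN_1650140 fell by 4.74 (SE 0.98, adjusted p = 0.0164) in IUGR rats, from 9.93 ± 0.18 (n = 6) in RND to 5.19 ± 0.07 (n = 3) in RHFD, while it lay at 5.72 ± 2.26 in CND and 6.17 ± 2.45 in CHFD. Among controls it was high in CND 38B on chow (10.32) and in CHFD 4A on high-fat diet (10.52) and low in all others. In control rats its level therefore did not follow diet.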
